A study of Homo sapiens with 6 samples.

How the data were processed

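Poly(A) RNA of human small airway epithelial cells was sequenced from 3 untreated samples and 3 samples given 40 ng/ml IL-9 for 6 h; RNA was taken with the RNeasy Plus Micro kit and libraries were made with the KAPA mRNA HyperPrep kit and sequenced paired-end, per the labels, which call hSAEC a cell line. The deposited table holds raw counts for 28058 genes, with gene symbols, exon coordinates, strand and length, in the column layout of featureCounts, per the file headers. The submitters' processing notes name FastQC, STAR, featureCounts, edgeR and the hg38 build without versions. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart, and counts of close paralogs are uncertain. The deposited length of each gene model is another value of the file, not a measurement, and was used solely in a check. All 6 columns were matched to samples by the names in the labels, and groups and replicate numbers were taken from the sample titles.

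Total counts were 20225964, 19458666 and 19124823 in untreated replicates 1, 2 and 3 and 20627018, 19309885 and 19616086 in IL-9 replicates 1, 2 and 3. One count equals 0.0485 to 0.0523 CPM at these depths; intervals and floors cover counting error only, since no molecular identifiers are described. Of all genes, 8733 had 0 counts in all libraries. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 13222 genes that held 99.9% of the counts of each library. TMM factors lay between 0.992 and 1.01. The counts were fitted in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit with robust estimation, group as the sole term), and Benjamini-Hochberg adjusted p below 0.05 was the threshold. Reported levels are CPM with TMM factors; log2 fold changes are IL-9 over untreated, and their SE was taken from the coefficient and its F statistic. The common biological coefficient of variation was 0.0853 without and 0.0351 with the replicate block.

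In all, 26 gene lists were fixed before the data were examined: chains of IL-9 and related cytokine receptors, JAK and STAT genes, STAT feedback genes, the airway response to IL-4 and IL-13, NF-kappaB inflammatory genes, type I interferon and interferon-gamma targets, immediate early genes, mucin and secretory, basal, ciliated, alveolar and club-like, squamous, junction, cell cycle, cholesterol, hypoxia, unfolded protein response, NRF2 and matrix genes, markers of fibroblasts, endothelium and blood cells, and mitochondrially encoded, histone and ribosomal protein genes. Of their symbols 43 were matched through an older symbol. No symbol of the 13 mitochondrially encoded mRNAs was matched in the deposited counts, so they could not be analysed. The 2 mitochondrial rRNA genes RNR1 and RNR2 took their place in the shares of counts, a choice made after the table was seen. The 23 lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01) and Benjamini-Hochberg adjustment over the lists. Of the 11 lists called, 3 held with a correlation estimated per list (NF-kappaB, squamous and junction genes) and 6 with fry, which tests whether a set's genes move on balance one way; fry's mixed test, for change in either direction, called 12. Neither form of fry compares a set with other genes. With the replicate block camera called 12 lists, 0 of them with an estimated correlation, and fry called 1. Not every lost call came with a higher correlation. Without the block, the estimate was below the preset 0.01 for the receptor chain (-0.0115), hypoxia (-0.00145), unfolded protein (-0.0234) and NRF2 (-0.0308) lists. It was above 0.01 for the STAT feedback (0.182), immediate early (0.135), fibroblast (0.233) and histone (0.135) lists. The NF-kappaB estimate was -0.011, also below the preset, yet camera's unadjusted p without the block went from 2.56e-41 to 9.23e-05 with it. Using an estimate thus changes more than the correlation. A call lost with an estimated correlation therefore does not show that correlation between genes had made the call.

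Genes named in the text were chosen by a rule fixed before the data were examined. The rule took a fixed set of receptor, JAK, STAT and feedback genes. It also took the 10 genes per direction with the largest change among those past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out unnamed loci and genes linked to the Y chromosome. From each list it took up to 4 members with the smallest p where the list or the member passed. Genes named outside the rule are given as such or as examples within a list.

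Because both groups carry replicate numbers 1 to 3, the number was also fitted as a block. The labels do not say what a number shares. The deviations of log2 CPM from the group means correlated at 0.51, 0.13 and 0.15 between libraries numbered 1, 2 and 3, all above the minimum of 0.1 set for treating the numbers as pairs, so blocked values are given where they change a call. The pairing rests on the data, and mainly on number 1: the untreated library numbered 2 correlated at 0.31 with the IL-9 library numbered 3, and 2 of the 6 libraries correlated best with their own number. The untreated library numbered 3 correlated at 0.154 with the IL-9 library numbered 2, against 0.151 with its own number. Deviations in a group sum to 0, so with number 1 apart, numbers 2 and 3 lean the same way in both groups. The rule therefore cannot show that numbers 2 and 3 are pairs. No 2 libraries agreed within sampling noise (chi-square per degree of freedom at least 2.43 for every pair), so none was taken as another library sequenced again. Separate libraries of the same culture would not be seen this way.

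The scripts were tested on simulated counts for the 13222 genes of this comparison, with 50 genes at each fold and a false share measured over all calls. Without the block, 82%, 76%, 94% and 98% of genes changed by 1.5, 2, 3 and 4-fold were recovered, with 13 false calls of 209; with the block these were 80%, 74%, 94% and 98%, with 17 false calls of 207. The simulated list that changed was called and 0 of 25 unchanged lists were. False calls made up 6.22% of calls without and 8.21% with the block, more than the adjusted p threshold is meant to allow. The block hardly changed the simulated calls (209 against 207), where in the data it took 20 genes to 459. The simulation therefore does not test what the block does in the data. Simulated counts were drawn independently for each gene, so the simulated lists held no correlated genes. Their result therefore does not decide on the preset correlation.

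The alternatives fixed before the data were examined were RLE, upper quartile and no normalization factors, DESeq2 1.42.0, limma-voom, other filters on low counts, fits without robust estimation, stricter thresholds (adjusted p 0.01, a fold of 1.2 tested with glmTreat, and an absolute log2 fold change of at least 1), the replicate block, other set tests and leaving out each library. Added after seeing the data were a term for the libraries numbered 1, fits without them, offsets that removed a per-library trend on transcript GC content (known for 98.1% of tested genes), the block with these offsets, and the block without each pair. Shares of counts were compared with exact two-sided permutation tests of 3 against 3 libraries.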

Results

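RNA sequencing measured how human small airway epithelial cells (hSAEC), cultured epithelial cells of the distal conducting airways, responded to interleukin-9 (IL-9), a cytokine secreted by T helper cells and other lymphocytes. Libraries of poly(A) RNA came from 3 samples treated with 40 ng/ml recombinant IL-9 for 6 h and 3 samples left without treatment. The series concerns the receptor that cells outside the blood lineage use for IL-9, so the levels of receptor chains and of their JAK and STAT partners were examined together with the response. Total counts per library ranged from 19124823 to 20627018, a ratio of 1.08 between the deepest and the shallowest library, and 13222 of 28058 genes were tested. The labels do not say whether the libraries of a group came from separate cultures or donors, so the p-values measure the spread between these libraries, which may be technical.

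Most receptor chains and all measured JAK and STAT genes were expressed. Of 34 receptor chains of IL-9 and related cytokines, 26 averaged at least 1 CPM (counts scaled to library size) over the 6 libraries, 5 lay below that level, and IL9R, IL2RA and CRLF2 had 0 counts. In untreated cells IL4R, the signalling chain shared by the IL-4 and IL-13 receptors, stood at 164 ± 5.02 CPM and IL13RA1 at 153 ± 7.43 CPM (SD, n = 3). IL2RG, the common gamma chain that pairs with the IL-9 receptor in blood cells, stood at 0.575 ± 0.0619 CPM. The kinase gene JAK1 was at 148 ± 2.88 CPM, TYK2 at 47.3 ± 5.26, JAK2 at 27.5 ± 2.52 and JAK3 at 2.47 ± 0.346. Among the transcription factor genes STAT3 was at 171 ± 6.67 CPM, STAT6 at 136 ± 5.86, STAT5B at 27.6 ± 0.707 and STAT5A at 3.22 ± 0.663. Without the block, none of the 11 JAK and STAT genes passed the edgeR threshold after IL-9, over all genes or adjusted over the list alone, and the list did not pass camera (adjusted p = 0.804). STAT5A had the largest log2 fold change of the 4 STAT genes named here, 0.58 ± 0.18 (SE), and counts that are uncertain because STAT5B is a close paralog. With the replicate number as a block, STAT5A did not pass over all genes (edgeR adjusted p = 0.0529) and was the 1 member higher when adjusted over the list alone (adjusted p = 0.0205).

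The count of 0 for IL9R does not measure its level. The gene lies in a region that the X and Y chromosomes share, and the table's hg38 gene models place it on chromosome X from 155997581 to 156010817 and on chromosome Y from 57184101 to 57197337. Of the 28 genes annotated on both chromosomes, 21 (75%) had 0 counts in all 6 libraries, against 31.1% of the other 28030 genes (Fisher's exact test, two-sided p = 2.27e-06). SLC25A6, an abundant mitochondrial carrier gene in most cells, was among those at 0. An upper limit from 3 counts, at most 0.157 CPM in the shallowest library, therefore does not apply to IL9R or to CRLF2, which lies in the same kind of region.

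After 6 h of IL-9, genes of the NF-kappaB list, among them the neutrophil-attracting chemokines CXCL8, CXCL1 and CXCL3, were among the 19 genes that rose. CXCL8 rose from 32.7 ± 1.98 to 64.1 ± 3.59 CPM, CXCL1 from 109 ± 6.61 to 193 ± 13.6 CPM and CXCL3 by 2.45-fold to 27.0 ± 1.08 CPM (SD, n = 3 per group). IL36G, an epithelial cytokine of the interleukin-1 family, had the largest fold change, 3.77-fold, to 5.31 ± 0.581 CPM, among the genes that passed. The most significant gene was SERPINB2, the plasminogen activator inhibitor type 2, at 1.93-fold, from 176 ± 6.93 to 340.5 ± 14.1 CPM. Without the replicate block, the sole gene that fell was CYP24A1, the vitamin D 24-hydroxylase, from 68.3 ± 0.761 to 51.3 ± 0.388 CPM.

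**Figure D1:**
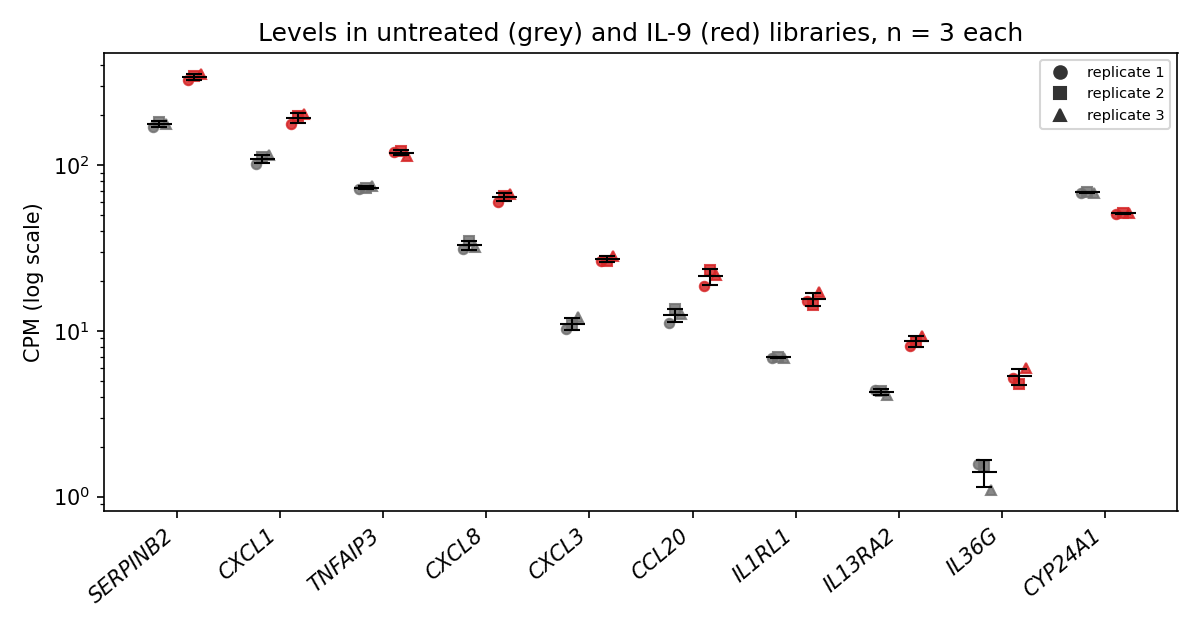
Levels of 10 genes past the threshold, in CPM on a log axis, for the 3 untreated libraries in grey and the 3 IL-9 libraries in red; symbols mark the replicate number, and bars give the mean and SD. The 3 IL-9 values lie above the 3 untreated values for 9 of the genes and below them for CYP24A1, for example 64.1 against 32.7 CPM on average for CXCL8.

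With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 20 genes passed an adjusted p of 0.05, of which 19 were higher and 1 lower. An unadjusted p under 0.05 was found for 840 genes. SERPINB2 (chromosome 18, 63887705 to 63903890, hg38) had a log2 fold change of 0.95 ± 0.06 (SE, edgeR adjusted p = 0.000688). The chemokine genes CXCL8 (chromosome 4, 73740506 to 73743716), CXCL1 (73869392 to 73871302) and CXCL3 (74036591 to 74038773) changed by 0.97 ± 0.07, 0.83 ± 0.07 and 1.29 ± 0.09 on the log2 scale, with edgeR adjusted p of 0.00123, 0.00297 and 0.00123. CXCL1, CXCL2 and CXCL3 are near-identical paralogs, and their counts are uncertain to the extent that reads were divided between them. TNFAIP3, which encodes the NF-kappaB inhibitor A20, rose by 0.70 ± 0.05 (edgeR adjusted p = 0.00123), and CCL20, a chemokine for dendritic cells and T cells, by 0.78 ± 0.11 (edgeR adjusted p = 0.0498). FLNC, the actin crosslinker filamin C, rose by 0.85 ± 0.12 (edgeR adjusted p = 0.0378). CYP24A1 (chromosome 20, 54153449 to 54173977) had a log2 fold change of -0.41 ± 0.05 (edgeR adjusted p = 0.0236). Named after their values were seen, further genes past the threshold included AKAP12, ALDH1A3, FST (the activin antagonist follistatin), BMP2, the EGF receptor ligands HBEGF and TGFA, IL1RN (the interleukin-1 receptor antagonist) and LINC00707, with log2 fold changes of 0.38 to 0.69. The groups did not overlap for 1687 genes, 12.8% of those tested, where chance gives 10%.

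With the replicate number as a block, 459 genes passed, 310 higher and 149 lower, and these held all 20 genes of the fit without the block. The labels do not give this pairing, and the correlations between libraries do not show it for numbers 2 and 3. The blocked changes were mostly small, with a median of 1.18-fold for the higher and 1.17-fold for the lower genes, and 35 of the 459 changed by at least 1.5-fold. Without the block, the count was 7 without untreated replicate 3 or without IL-9 replicate 2, 9 without untreated replicate 2 or without IL-9 replicate 3, and 31 without untreated replicate 1. SERPINB2, CXCL3, TNFAIP3, CXCL8, CXCL1, IL1RL1 and IL36G passed in all 6 fits that left out a library, while CYP24A1, CCL20 and FLNC passed in 1 of the 6; with the block, leaving out the pair numbered 1 gave 165 genes.

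Both receptor chains that passed the threshold were higher after IL-9. IL1RL1, the receptor for IL-33 (chromosome 2, 102311502 to 102352037), rose from 6.91 ± 0.0618 to 15.5 ± 1.42 CPM (SD, n = 3), a log2 fold change of 1.17 ± 0.10 (SE, edgeR adjusted p = 0.00339). IL13RA2, a second receptor for IL-13 that is regarded mainly as a decoy (chromosome X, 115003975 to 115017644), rose from 4.27 ± 0.173 to 8.66 ± 0.642 CPM, by 1.02 ± 0.11 (edgeR adjusted p = 0.0146). This call was lost in 4 of the 6 fits without one library. The other 25 tested chains of the list did not pass; adjusted over the list alone, 3 were higher, with OSMR as the third, and 1, IL20RB, was lower. With the block, OSMR (log2 fold change 0.19, edgeR adjusted p = 0.00256) and IL20RB (-0.33, edgeR adjusted p = 0.0104) passed over all genes. IL4R, IL13RA1 and IL2RG had log2 fold changes of 0.02 ± 0.06, -0.02 ± 0.06 and 0.26 ± 0.35. Camera called the list as higher (adjusted p = 0.00218), although its median log2 fold change was 0.02 and its mean 0.10. Of the 27 tested chains, 16 had a log2 fold change above 0. The list was not called with an estimated correlation (adjusted p = 0.0891 with an estimated correlation) and not without untreated replicate 1 (adjusted p = 0.0664).

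Inflammatory genes of the NF-kappaB pathway rose as a group. Of the 39 tested members of the list, 7 were higher over all genes tested, 0 were lower and 32 did not pass. Adjusted over the list alone, 21 were higher and 2 lower, and with the block 18 were higher and 1 lower over all genes. The median log2 fold change of the list was 0.26, and camera called it as higher (adjusted p = 5.88e-40), also with an estimated correlation (adjusted p = 0.00212 with an estimated correlation). In the blocked fit camera gave an adjusted p of 0.0891 with an estimated correlation, and fry an adjusted p of 0.0161. Among members that passed with the block alone, and named after their values were seen, CXCL5 changed by 0.86 (edgeR adjusted p = 2.66e-08), CSF3 by 0.98 (0.00171), BIRC3 by 0.76 (0.00343) and CXCL2 by 0.51 (0.00370) on the log2 scale. Members NFKBIA, NFKBIZ, TNIP1, ICAM1, NFKB1, NFKB2 and RELB changed by 0.20 to 0.49. LCN2, the antibacterial protein lipocalin 2, was the lower member at -0.37 (edgeR adjusted p = 0.00226). IL1B and IL6 had blocked edgeR adjusted p of 0.0613 and 0.0673.

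Squamous, junction and immediate early gene lists were also called as higher by camera, with median log2 fold changes of 0.10, 0.06 and 0.13. Of 28 squamous and cornified envelope genes none passed over all genes without the block, and 6 were higher when adjusted over the list alone. With the block 5 were higher, among them EMP1 (log2 fold change 0.40, edgeR adjusted p = 8.14e-07) and the keratin gene KRT6B (0.53, edgeR adjusted p = 3.77e-08). SPRR2D and SPRR2A, cornified envelope precursors, had blocked edgeR adjusted p of 0.00122 and 0.0148; KRT6B and the SPRR2 genes have close paralogs, so their counts are uncertain. The camera adjusted p of this list was 1.71e-07 (adjusted p = 0.0349 with an estimated correlation, and adjusted p = 0.223 with an estimated correlation in the blocked fit). Of 24 epithelial junction genes, 3 were higher adjusted over the list alone, and 5 were higher with the block, with log2 fold changes of 0.67 for CGN, 0.55 for CLDN4 and 1.02 for OCLN. The junction list had a camera adjusted p of 1.74e-06 (adjusted p = 0.0349 with an estimated correlation, and adjusted p = 0.223 with an estimated correlation in the blocked fit). Of 27 immediate early genes none passed without the block, 6 were higher and 1 lower adjusted over the list alone. With the block 6 were higher and 2 lower, with DUSP4 at 0.23, DUSP5 at 0.35 and FOSL1 at 0.36 against BTG2 at -0.23. The immediate early list was called at an adjusted p of 5.01e-05 and lost that call with an estimated correlation (adjusted p = 0.180 with an estimated correlation).

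The STAT feedback genes gave a smaller signal. SOCS3, a feedback inhibitor of JAK and STAT signalling, went from 6.59 ± 0.152 to 9.73 ± 0.605 CPM (SD, n = 3), a log2 fold change of 0.56 ± 0.10 with an edgeR adjusted p of 0.130, and passed with the block (edgeR adjusted p = 0.00448). SOCS1 lay near the floor of detection, at 0.556 ± 0.239 and 1.21 ± 0.280 CPM (edgeR adjusted p = 0.550, and 0.0766 with the block). CISH, BCL3 and PIM1, known target genes of STAT5 or STAT3, had log2 fold changes of -0.10 ± 0.22, 0.13 ± 0.17 and 0.18 ± 0.07, and did not pass with either fit. Of the 23 tested genes of the list none passed over all genes, and 2 were higher adjusted over the list alone. With the block 3 were higher (SOCS3, DUSP5 and FOSL1) and 2, PTPN6 and CCND2, were lower. DUSP5 and FOSL1 are also members of the immediate early list, so they do not mark STAT feedback alone. Camera called the list as higher at an adjusted p of 0.00800, and not with an estimated correlation (adjusted p = 0.425 with an estimated correlation), nor without untreated replicate 2 (adjusted p = 0.0662) or IL-9 replicate 1 (adjusted p = 0.253). The 31 genes of the unfolded protein and integrated stress responses were called as higher at an adjusted p of 0.00396 (adjusted p = 0.0891 with an estimated correlation); none passed without the block, 1 was higher adjusted over the list alone. With the block HERPUD1 (0.37), the chaperone gene HSPA5 (0.16) and SDF2L1 (0.26) were higher and SLC7A11 (-0.18) lower.

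**Figure D2:**
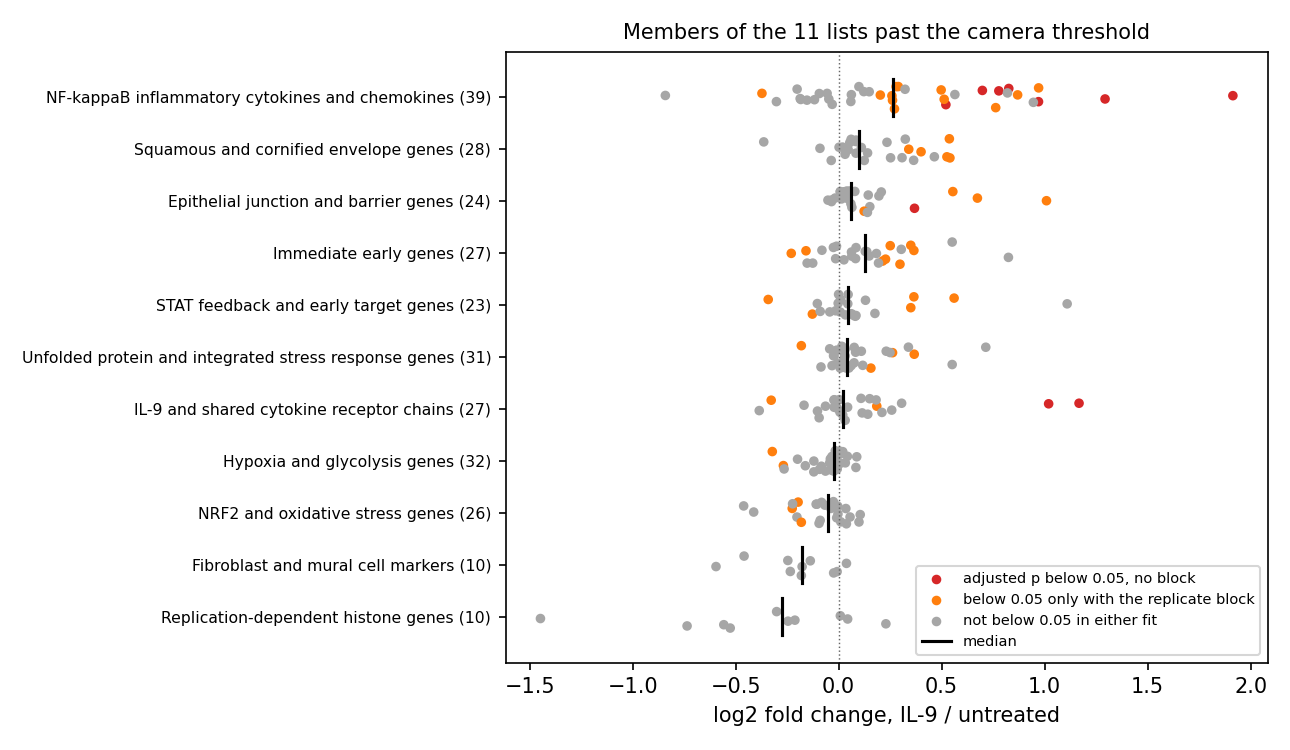
Log2 fold changes (IL-9 over untreated, x axis) of the tested members of the 11 gene lists past the camera threshold, with the number of members in brackets and the median as a black bar. Red points passed without a block and orange points with the replicate block alone; the NF-kappaB list has the highest median, 0.26, and the histone list the lowest, -0.27.

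Camera called 4 lists as lower, with median log2 fold changes from -0.27 to -0.02, and none of them with an estimated correlation. Of 26 NRF2 and oxidative stress genes none passed over all genes or adjusted over the list alone without the block. With the block GCLC (log2 fold change -0.20), which makes glutathione precursors, AKR1C3 (-0.23) and SLC7A11 (-0.18) were lower (camera adjusted p = 0.00396, and adjusted p = 0.0891 with an estimated correlation). Of 32 hypoxia and glycolysis genes 1 was lower adjusted over the list alone, and with the block DDIT4, an mTOR inhibitor, was lower at -0.32 (edgeR adjusted p = 3.17e-06) and EGLN3 at -0.27 (camera adjusted p = 0.0407, and adjusted p = 0.180 with an estimated correlation). The hypoxia list lost its call without untreated replicate 1 (adjusted p = 0.260), IL-9 replicate 2 (0.0774) or IL-9 replicate 3 (0.303). Of 10 tested fibroblast and mural cell markers none passed with either fit; the median log2 fold change was -0.18, with COL3A1 at -0.60 ± 0.20, COL1A2 at -0.25 ± 0.10, ACTA2 at -0.23 ± 0.13 and TAGLN at 0.04 ± 0.06 (camera adjusted p = 0.00493, and adjusted p = 0.292 with an estimated correlation). Without untreated replicate 1 the fibroblast list had an adjusted p of 0.0984. Of 10 tested histone genes 1, HIST1H4C, was lower adjusted over the list alone, with means of 0.750 and 0.269 CPM; the list's camera adjusted p was 0.00286 (adjusted p = 0.180 with an estimated correlation). With at least 1 CPM in 3 libraries required, the histone list had an adjusted p of 0.257.

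The list of airway epithelial genes responsive to IL-4 and IL-13 stood at the threshold. Of its 15 tested genes SERPINB2 was higher and 14 did not pass; adjusted over the list alone 3 were higher and 2 lower, and with the block SERPINB2 and IL33 were higher and POSTN and SERPINB13 lower. The camera adjusted p was 0.0501 without the block and 0.00758 with it, both in the upward direction (adjusted p = 0.180 without and 0.336 with the block, both with an estimated correlation), although the median log2 fold change was -0.04 and the mean 0.09. Without IL-9 replicate 1 the list passed (adjusted p = 0.0158).

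The other tested lists did not pass camera, and none of their members passed over all genes without the block. The camera adjusted p was 0.677 for 30 type I interferon-stimulated genes, 0.770 for 14 interferon-gamma targets, 0.438 for 13 mucin and secretory cell genes, and 0.804 for 21 basal cell genes. It was 0.709 for 10 ciliated cell genes, 0.588 for 9 alveolar and club-like genes, 0.455 for 40 cell cycle genes, 0.677 for 25 cholesterol synthesis genes, 0.2005 for 32 matrix and mesenchymal transition genes and 0.528 for 56 ribosomal protein genes. The ribosomal list was called as higher without IL-9 replicate 1 (adjusted p = 0.00402) and as lower without IL-9 replicate 2 (adjusted p = 0.0021), and was not called without both libraries numbered 1 (adjusted p = 0.357). In a comparison chosen after the data were seen, this list was lower in the 2 libraries numbered 1 than in the other 4 (median log2 fold change -0.17, camera adjusted p = 9.97e-20), and no other list passed there. The basal cell genes TP63 and KRT5 were at 436 and 10786 CPM in untreated cells, with log2 fold changes of -0.03 ± 0.07 and 0.01 ± 0.06. Within the matrix list, 4 genes were higher and 1 lower adjusted over the list alone; with the block 8 were higher, including PLAU (0.35), PLAUR (0.44) and MMP1 (0.37), and 2 were lower. Of 22 blood and immune cell markers CD68 and CD4 were tested and neither passed, PTPRC and TYROBP had 0 counts, and LYZ had at most 2 counts in a library. Of 10 endothelial markers 1, TEK, was tested and did not pass.

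Shares of counts taken by ribosomal protein, mitochondrial rRNA and the most abundant genes were close in both groups. Ribosomal protein genes took 3.88% ± 0.131 of the counts in untreated and 3.81% ± 0.276 in IL-9 libraries (SD, n = 3; exact two-sided permutation p = 0.9). The 20 most abundant genes took 11.91% ± 0.213 and 12.02% ± 0.321 (exact p = 0.7, n = 3), and the mitochondrial rRNA genes RNR1 and RNR2 0.569% ± 0.127 and 0.489% ± 0.0337 (exact p = 0.4, n = 3). Histone genes took 0.00598% ± 2.5e-05 and 0.00517% ± 0.000516 (exact p = 0.1, n = 3), where 0.1 is the smallest exact p that 3 against 3 allow. Benjamini-Hochberg adjustment over these 4 exact tests gave p of 0.4 or more.

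**Figure D3:**
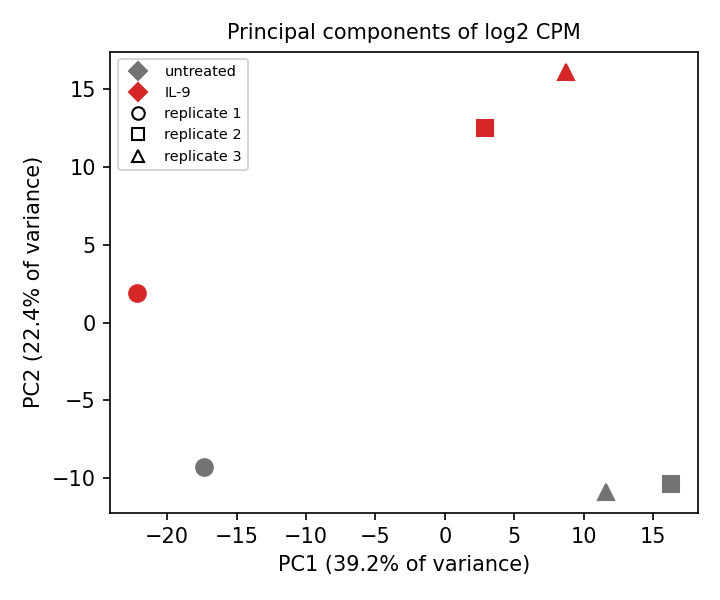
First and second principal components of the log2 CPM of the tested genes (x axis 39.2% and y axis 22.4% of the variance), grey for untreated and red for IL-9 libraries, with symbols for the replicate number. The first component sets both libraries numbered 1 apart from the other 4, and the second sets the IL-9 libraries above the untreated ones.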

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

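Fits with the term for libraries numbered 1, without those libraries, with GC offsets, and with the block and GC offsets or without a pair were chosen after the data were seen. The count of 20 genes was 18 to 20 with RLE, upper quartile or no factors, limma-voom, at least 1 CPM in 3 libraries, or no robust estimation. It was 58 (52 higher, 6 lower) with DESeq2, 42 (39 and 3) with no filter, 9 (9 and 0) at adjusted p 0.01, 8 (8 and 0) with glmTreat and 4 (4 and 0) at an absolute log2 fold change of at least 1, where the stricter rule itself lowers the count. It was 459 (310 and 149) with the replicate block, 580 (378 and 202) with a term for the libraries numbered 1, 216 (149 and 67) without both of them, 124 (107 and 17) with GC offsets, and 756 (449 and 307) with the block and GC offsets. With the block it was 165 (117 and 48) without pair 1, 523 (325 and 198) without pair 2 and 575 (395 and 180) without pair 3. Leaving out 1 library without the block gave 7 to 31 genes, 7 to 21 higher and 0 to 10 lower: 31 without untreated replicate 1, 7 without untreated replicate 3 or IL-9 replicate 2, and 9 without untreated replicate 2 or IL-9 replicate 3. All 20 genes passed with DESeq2, the block, GC offsets, both together and the number 1 term, and 19 with limma-voom. Of the lists, 3 passed with an estimated correlation and 6 with fry, against 11. The NF-kappaB list passed in every alternative that was run on the lists, except the blocked fit with an estimated correlation.

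Signs turned for results that had not passed, many of them close to 0. IL2RG (0.26), BCL3 (0.13) and CISH (-0.10) lay farther from 0 in the fit without the block and also turned. The log2 fold change of JAK3 was -0.006675 with upper quartile factors, -0.006846 with library totals, -0.01058 with limma-voom, -0.001676 with the block, -0.01185 with GC offsets and -0.02046 with both. IL4R was at -0.002758 with GC offsets and -0.001824 with both, and the basal cell list mean at -0.01393 and -0.01385. Without both libraries numbered 1, IL2RG was at -0.001523, IL4R at -0.004413, and the list means were 0.02643 (JAK and STAT), -0.001622 (type I interferon), -0.01734 (basal cell) and 0.01251 (ribosomal). Over the fits without 1 library, STAT3 ranged from -0.05225 to 0.002711, IL4R from -0.0223 to 0.05301, IL13RA1 from -0.05991 to 0.0183 and JAK2 from -0.08656 to 0.04694. JAK3 ranged from -0.1919 to 0.13, IL2RG from -0.08299 to 0.42, TYK2 from -0.04087 to 0.17, BCL3 from -0.03506 to 0.26 and CISH from -0.29 to 0.07526. List means ranged from 0.01065 to 0.08196 (interferon-gamma), -0.02537 to 0.01346 (basal), -0.08336 to 0.0478 (ribosomal) and 0.01521 to 0.05045 (JAK and STAT). They ranged from -0.01421 to 0.04381 (type I interferon), -0.11 to -0.01868 (ciliated) and -0.02545 to 0.01152 (cholesterol); where camera's direction turned, the mean kept its sign in some. The ribosomal list passed as higher without IL-9 replicate 1 (adjusted p = 0.00402), and as lower without IL-9 replicate 2 (adjusted p = 0.0021) and with the block and GC offsets (adjusted p = 0.0333). Without both libraries numbered 1 the STAT feedback list did not pass (adjusted p = 0.1245) and the list for IL-4 and IL-13 did (adjusted p = 0.00447), as it did with library totals (0.0334), the number 1 term (0.00276), GC offsets (0.00769) and the block with GC offsets (0.00182). The cause was not tested. Counts per named gene near 1 CPM, such as IL2RG with 75 counts in all, limit what its fold change can show.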

Other observations

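The tests of shared X and Y reads, of blood cells, of a missing mock control and of GC content as the whole cause were chosen after the result was seen, as were the genes and groups of this part. Among 15 tested ligands and antagonists of the activin, BMP and WNT pathways, FST and BMP2 rose without the block and 5 rose with it, and the other 10 did not pass. Without the block and without one library, FST passed in 2 of 6 fits and BMP2 in 0. FST went from 341 ± 8.36 to 488 ± 24.5 CPM (SD, n = 3), and INHBA, which encodes the activin A subunit that follistatin binds, from 119 ± 11.1 to 176 ± 18.0 CPM (edgeR adjusted p = 0.0832, and 1.21e-08 with the block). DKK1 and WNT7B changed by 0.25 and 0.41 on the log2 scale with the block (edgeR adjusted p = 0.000287 and 4.12e-05). Among 6 ligands of the EGF receptor, HBEGF and TGFA rose without the block, each in 2 of the 6 fits without one library, and EREG rose with it. BTC and EPGN did not pass, and AREG, the most abundant of those named here, was at 601 ± 10.5 and 627 ± 8.31 CPM (blocked edgeR adjusted p = 0.395). Of 16 tested ERK feedback genes 5 rose with the block, among them DUSP4, DUSP5, FOSL1 and SPRY2, and ETV5 fell. DUSP4, DUSP5 and FOSL1 also belong to the immediate early list, and DUSP5 and FOSL1 to the STAT feedback list. In the urokinase system SERPINB2, PLAU and PLAUR, that is inhibitor, protease and receptor, rose together with the block. These groups were built around genes already seen to pass, so no test of the groups is given.

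Genes lower with the block included SESN3, a stress-responsive regulator of mTOR, from 107 ± 11.6 to 77.7 ± 5.71 CPM (edgeR adjusted p = 3.40e-07), and CDKN2B, a cell cycle inhibitor induced by TGF-beta, from 51.7 to 40.2 CPM (edgeR adjusted p = 0.000121). TGFB2, ID3, TXNIP and FOXO4 had blocked log2 fold changes of -0.34, -0.35, -0.17 and -0.56 (edgeR adjusted p = 0.00208, 0.00417, 0.00436 and 0.0220).

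IL9R had 0 counts in all libraries, although 20 genes differed between the IL-9 and untreated libraries. A possible explanation is that reads shared between the X and Y copies of the pseudoautosomal regions were not counted, since 6 of 8 widely expressed genes annotated on both chromosomes were also at 0. IL9R may therefore be expressed or not, and IL2RG at 0.575 CPM and IL4R at 164 CPM in untreated cells leave open which chains would carry a signal.

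Inflammatory genes rose after IL-9 in the fit without the block. The median log2 fold change of the NF-kappaB list was 0.25 with library totals against 0.26. TMM factors lay between 0.992 and 1.01 and could hardly move it. The comparison therefore shows only that the choice between these normalizations mattered little. GC content bias does not account for the rise, since 0.235 was left after its removal. Blood or immune cells in the IL-9 cultures are argued against by at most 2 counts in a library for PTPRC, LYZ and TYROBP together. The series holds 0 libraries of mock-treated wells, so an effect of IL-9 and of handling of the treated wells without a vehicle control cannot be told apart. The hypothesis that IL-9 acts through NF-kappaB in these cells stays open, as no inhibitor of the pathway was used in the samples analysed here.

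The libraries numbered 1 stood apart in both groups, with 3858 genes past the threshold between them and the other 4 (2037 higher, 1821 lower). GC content bias may be part of this, since GC offsets left 1850 genes, just under the limit of 50% set before the result was seen, and the genes higher in number 1 had a median GC content of 59.6% against 41.1% for the lower ones. As removed here it is not the whole cause, because 47.95% of the genes were left, where at most 5% would be, a limit that replaced another one after this value was seen. Length bias is argued against, with 3869 genes left after offsets on gene model length. Thinning to the smallest total left 3832 genes. Library totals differed by a ratio of 1.08 at most, so thinning could hardly lower the count and does not decide on library size. A shared culture, donor or day for the same number was not tested, since the labels name none.

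The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 20 genes and the highest other split 1, so that 1 of 10 splits gave as many genes. With the block, 1 of the 4 splits that part all pairs gave as many, with 459 genes against 0 at most in the others. For the gene lists 1 of 10 splits gave as many, with 11 lists against 5 in the highest other.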
